A study of Mus musculus with 6 samples.

How the data were processed

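RNA was sequenced from neutrophils sorted by flow cytometry from infected mouse corneas, in 3 wild-type and 3 Il1a knockout libraries. Per the labels' protocols, RNA was purified with a column kit and libraries were made with the SMART-Seq v4 low-input kit, which amplifies full-length cDNA and does not mark strand. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39 and STAR 2.7.8a and the builds GRCm38 and mm10. The annotation release and any filter are not given in the sources used here. The authors deposited whole-number gene counts per library, not normalized, with an unstranded column and 2 columns by read strand in the layout of STAR. Between 49.9% and 50.1% of the stranded counts fell in the former of the strand columns, and the unstranded column was used for the main results. In that layout reads in overlapping gene models are left out of the unstranded count.

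Of 54838 genes in the tables, 54809 had an entry in GENCODE M21, which gave symbols, positions, lengths and GC content and may not be the release the authors used. Totals ranged from 22855676 to 33626008 counts per library. Genes were kept by edgeR's default expression filter by group, which left 11924 genes with 99.9% of the counts. The lowest tested genes rest on few counts, and counting intervals cover counting error only, since reads were not tagged by molecule.

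Counts were normalized by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood test, limma 3.58.1, R 4.3.3), knockout against wild type, without a term for the replicate number. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM are counts scaled to the TMM-adjusted library size, log2 CPM used a prior count of 3, and values are mean ± SD. With 3 libraries per genotype, an exact permutation test of a single value cannot give a two-sided p below 0.1. For a gene with few counts in a group, the ratio of counts is given with a 95% exact counting interval.

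Before the data were examined, 27 pathway lists and 11 cell marker lists were fixed, as were the test, most of the other settings tried and the rule for naming genes. The lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, each kind adjusted as a family. Of 788 pathway and 190 marker entries with distinct symbols, 787 and 190 matched the annotation, older symbols included. The rule named Il1a, then up to 12 called genes per direction with a mean of at least 5 CPM, a plain symbol and groups that do not overlap. It further named up to 4 members per pathway list with the smallest p, the 3 most abundant members per marker list and the tested neighbours of Il1a within 1 Mb. Other genes are said in the text to have been chosen after their values were seen.

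The procedure was tested on counts simulated from the means and library sizes of these data. In them 200 genes with a mean of at least 5 CPM were changed, and 23 members of 1 list were raised by 0.5 on the log2 scale. It called 11, 35, 50 and 50 of the 50 genes changed 1.5-, 2-, 4- and 8-fold. Beside these it called 20 of 11174 unchanged genes, and 1 of 26 unchanged lists. Transcripts of tested genes were searched against those of genes within 15 Mb of Il1a with blastn 2.17.0, and a copy was counted at 90% identity or more over at least 50% of the transcript.

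The other settings fixed in advance were DESeq2 size factors, upper quartile scaling, library size alone, no filter, a filter at 5 CPM in 3 libraries, a replicate block with and without a GC and length offset (mgcv 1.9.3), the offset alone, each library left out, the strand columns, a minimum fold of 1.5, removal of marker genes of other cells, limma-voom and DESeq2 1.42.0. Removal of the genes near Il1a, and the list alternatives for the marker lists, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.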

Results

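Gene expression was measured by RNA sequencing in neutrophils sorted from mouse corneas 24 h after infection with PAO1, a laboratory strain of the bacterium Pseudomonas aeruginosa. The neutrophils came from wild-type mice or from mice lacking Il1a, which encodes the inflammatory cytokine IL-1 alpha, with 3 libraries per genotype. The libraries held 25721159, 31768433 and 33626008 gene counts in wild type and 30229879, 32295293 and 22855676 in the knockout. Pearson correlations of log2 CPM (counts normalized to library size) across genes lay between 0.946 and 0.972 for all pairs of libraries, and the values within and between genotypes overlapped. Knockout replicate 2 stood apart on the first principal component, at 67.3 against -32.9 to 2.1 for the other 5 libraries (32.1% of the variance). The labels number biological replicates but name no animals, so the p-values describe the spread between these libraries. The question the design poses is how loss of IL-1 alpha changes the neutrophil transcriptome during corneal infection.

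Il1a (ENSMUSG00000027399, GRCm38 chromosome 2, 129299610 to 129309972, minus strand) fell from 6696 ± 1881 CPM in wild type to 4.47 ± 1.37 CPM in the knockout (SD, n = 3 each). The wild-type libraries held 136694, 192428 and 272865 Il1a counts, and the knockout libraries held 92, 174 and 118. Each library therefore carried the Il1a level of its label. The log2 fold change was -10.55 (SE 0.35, edgeR quasi-likelihood test, adjusted p = 5.3e-07). In wild type, Il1a made up 0.650% ± 0.145 (SD, n = 3) of all gene counts. A gene-level count does not show which exons the remaining knockout reads come from.

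The other IL-1 family genes did not pass the test in either direction. Il1b, the gene of IL-1 beta, was at 22365 ± 1285 CPM in wild type and 20217 ± 2390 CPM in the knockout, with a log2 fold change of -0.15 and a 95% interval from -0.40 to 0.11. Il1rn, which encodes the IL-1 receptor antagonist and was singled out after its values were seen, was at 20503 ± 2528 and 18666 ± 718 CPM. Il1rap, the shared receptor subunit, was at 1348 ± 191 and 1173 ± 77 CPM (log2 fold change -0.20). Il18 was at 14.9 ± 4.4 and 11.8 ± 1.8 CPM, and the signalling receptor Il1r1 was near the detection limit at 1.19 and 0.64 CPM. Of 15 tested members of this list, 0 passed over all genes and 0 adjusted over the list alone (camera, adjusted p = 0.19).

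**Figure D1:**
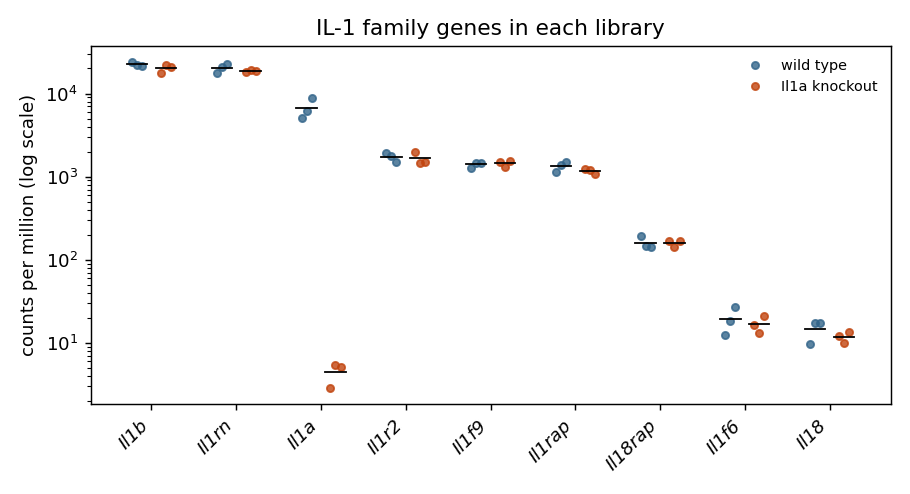
Expression in CPM (log scale) of Il1a and of the IL-1 family genes with a mean of at least 10 CPM, for 3 wild-type and 3 Il1a knockout libraries. Points are libraries and bars are group means. Il1a is the only plotted gene whose groups lie far apart, at 6696 against 4.47 CPM, and Il1f6 and Il1f9 are the annotation's names for the genes of IL-36 alpha and IL-36 gamma.

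Across 11924 tested genes, 12 changed between the genotypes at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 9 higher and 3 lower in the knockout. At an unadjusted p under 0.05 there were 714 genes. The groups did not overlap for 11.6% of the tested genes, against the 10% that chance gives for 3 against 3. Of the 12 changed genes, 10 lay on chromosome 2 within 15 Mb of Il1a, a distance chosen after the positions were seen. Without the 179 tested genes of that region, 1 gene was called, and at an unadjusted p under 0.05 there were 672. The count changed when single libraries were left out. It was 7 without wild-type replicate 1, 7 without wild-type replicate 2 and 24 without knockout replicate 1. Fewer libraries also lower the power of the test, so a lower count does not by itself show dependence on the library left out. DESeq2 called 70 genes.

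Close to Il1a, 2 neighbours fell with it. Ckap2l, which encodes a mitotic spindle protein, lies 2397 bases beyond the 3′ end of Il1a on the same strand (chromosome 2, 129268210 to 129297212) and fell from 49.1 ± 4.5 to 0.68 ± 0.52 CPM (SD, n = 3 each; log2 fold change -6.11, SE 0.38, edgeR adjusted p = 6.3e-05). Gm14023, an antisense transcript that overlaps 8217 bases of the Il1a gene (129297370 to 129307826, plus strand), fell from 142 ± 10 to 20.3 ± 5.7 CPM (log2 fold change -2.81, SE 0.20, edgeR adjusted p = 9.4e-05). The library kit does not mark strand, and the count used leaves out reads where the 2 genes overlap, so the size of the change in Gm14023 is uncertain. The sum of the strand columns gave Gm14023 42897 to 83351 counts in wild type and 660 to 918 in the knockout. There a read in the overlap counts to both genes. In wild-type replicate 1, Gm14023 went from 3704 unstranded counts to 42897, and Il1a from 136694 to 175908. The sum therefore largely repeats the fall of Il1a and does not give the size of the change in Gm14023. Over the alternatives run, strand columns included, the log2 fold change of Gm14023 ranged from -6.18 to -2.65. Among the other tested neighbours within 1 Mb, Stk35, a kinase gene, was at 9.38 ± 0.75 and 18.9 ± 3.6 CPM and Slc20a1, a phosphate transporter gene, at 84.0 ± 19.5 and 71.6 ± 9.9 CPM, and neither passed the test, although Stk35 was called without a filter and by DESeq2.

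At 120 to 123 Mb on the same chromosome, 7 genes rose in the knockout. Snap23, which encodes a membrane fusion protein used in granule release, was the most abundant and rose from 611 ± 44 to 1121 ± 113 CPM (SD, n = 3 each; log2 fold change 0.88, SE 0.12, edgeR adjusted p = 0.020). Haus2, a gene of the spindle-organising augmin complex, rose from 4.0 ± 0.7 to 30.03 ± 3.43 CPM (log2 fold change 2.91). Tmem87a rose from 3.73 ± 1.20 to 18.3 ± 4.1 CPM, Ehd4, an endosomal trafficking gene, from 6.91 ± 1.82 to 22.3 ± 2.5 CPM, and Bloc1s6, a gene of lysosome-related organelle assembly, from 16.6 ± 2.6 to 36.1 ± 1.4 CPM. Stard9, which was chosen after its values were seen, rose from 0.92 ± 0.24 to 8.24 ± 0.75 CPM. The calls of Snap23 and Bloc1s6 were lost in 6 of 6 fits that left out a library, with adjusted p up to 0.15 and 0.17. The call of Ehd4 was lost in 5 of them, all but the fit without knockout replicate 1 (adjusted p up to 0.16). That of Tmem87a was lost without wild-type replicate 1 (0.075) or 2 (0.072). Across the fits with a library left out, the log2 fold change was 0.80 to 0.95 for Snap23 and 1.00 to 1.24 for Bloc1s6. It was 1.48 to 1.85 for Ehd4 and 2.10 to 2.59 for Tmem87a.

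The remaining gene of that stretch, Gm14085, and 2 genes on other chromosomes resemble genes near Il1a in sequence, so their values are uncertain; all 3 were chosen after their values were seen. Gm14085 had 1, 0 and 0 counts in the wild-type libraries and 628, 480 and 315 in the knockout libraries, a ratio of 1451 with a 95% counting interval from 260 to 57364. Its transcript matched that of Slc28a2, a nucleoside transporter gene on chromosome 2, at 95.9% identity. Pcna-ps2, a processed pseudogene on chromosome 19, rose from 0.15 ± 0.02 to 2.76 ± 0.33 CPM and matched Pcna at 99.2%. Eif3j2 on chromosome 18 rose from 1.03 ± 0.31 to 6.12 ± 0.66 CPM (SD, n = 3 each) and matched Eif3j1 at 99.4%. Its call was lost without wild-type replicate 1 (0.067), 2 (0.067) or 3 (0.055) or knockout replicate 3 (edgeR adjusted p = 0.080). Slc28a2, Pcna and Eif3j1 lie within 15 Mb of Il1a and were not called. Eif3j1 was at 13.6 ± 0.8 CPM in wild type and 7.86 ± 0.96 CPM in the knockout, and Pcna at 15.9 ± 3.1 and 12.9 ± 1.9 CPM. The summed level of each pair was 14.7 ± 0.5 CPM in wild type and 13.99 ± 1.63 CPM in the knockout for Eif3j1 and Eif3j2, 16.0 ± 3.1 and 15.7 ± 2.1 CPM for Pcna and Pcna-ps2, and 35.0 ± 9.7 and 92.0 ± 13.6 CPM for Slc28a2 and Gm14085, where Slc28a2 itself was at 35.0 ± 9.7 and 75.9 ± 10.5 CPM (edgeR adjusted p = 0.12).

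**Figure D2:**
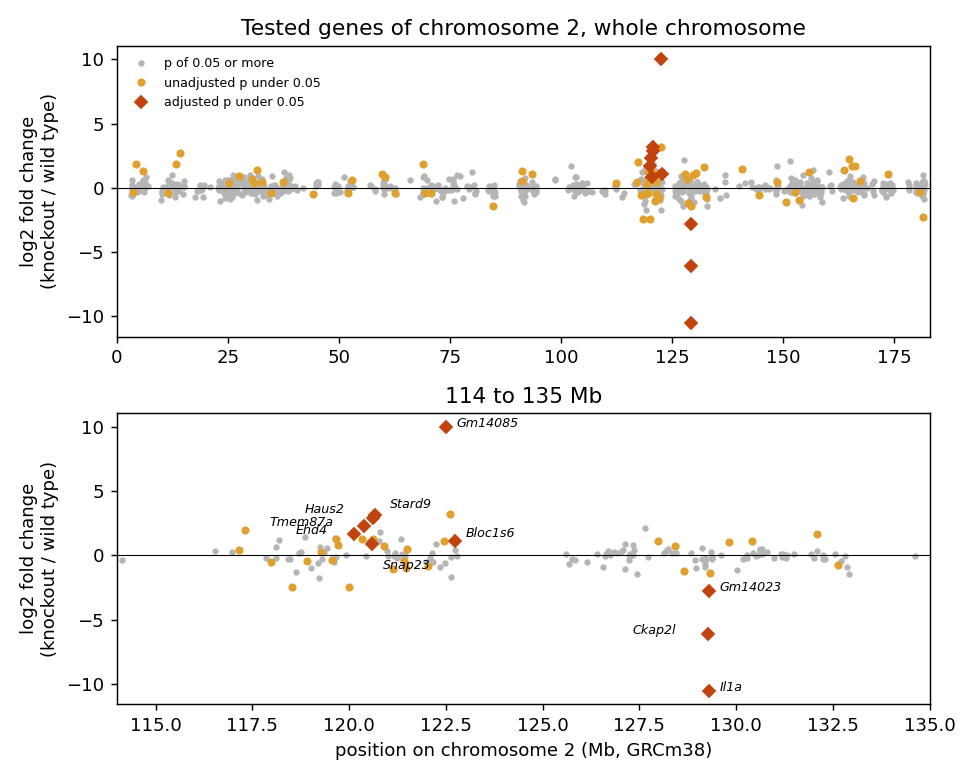
Log2 fold change (knockout over wild type) of tested genes against their position on chromosome 2 (Mb, GRCm38), for the whole chromosome and, enlarged, for the region around Il1a. Points are genes, and diamonds mark the 10 genes at an adjusted p under 0.05, which all lie between 120 and 130 Mb.

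The most abundant transcripts were not called. Fth1, the ferritin heavy chain gene, was at 50951 ± 5191 and 49246 ± 3235 CPM, Cd14 at 32856 ± 4185 and 29075 ± 229 CPM, and the chemokine gene Cxcl2 at 24092 ± 1985 and 23092 ± 4535 CPM (SD, n = 3 each), all 3 named after their values were seen. Among 1848 uncalled genes with a mean of at least 50 CPM, the 95% interval lay within a 2-fold change in either direction for 99.0%, with a median half-width of 0.30 on the log2 scale. In counts simulated from these libraries with 200 genes changed, the test recovered 22% of genes changed 1.5-fold, 70% changed 2-fold and 100% changed 4-fold. An adjusted threshold is easier to reach when many genes change, and 12 genes were called in the data. Recovery in the data may therefore be lower. The genes changed in the simulation had a mean of at least 5 CPM, so recovery among the lower tested genes was not measured.

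Among 27 gene lists fixed before the data were examined, 1 was called by camera with a preset correlation. The unfolded protein and integrated stress response list was lower in the knockout (adjusted p = 0.0043, median log2 fold change -0.14). It was not called with an estimated correlation (adjusted p = 0.74) or by fry (adjusted p = 0.71), nor by camera without knockout replicate 3 (adjusted p = 0.089). Of its 25 tested members, 0 passed over all genes in the main test (Dnajb9 did without a filter and by DESeq2) and 5 fell adjusted over the list alone. These were endoplasmic reticulum folding genes: Dnajb9 fell from 201 ± 23 to 139 ± 13 CPM, Dnajc3 from 25.1 ± 3.1 to 16.7 ± 1.1 CPM, Pdia6 from 151 ± 24 to 107 ± 7 CPM, Manf from 52.3 ± 9.5 to 35.9 ± 2.5 CPM, and Hspa5, named after its values were seen, from 3833 ± 565 to 2885 ± 189 CPM.

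The lists of inflammatory signalling did not pass. For NF-kB target genes 0 of 41 members passed over all genes and 0 adjusted over the list alone (camera, adjusted p = 0.58), with Tnf at 838 ± 85 and 1012 ± 185 CPM and Nfkbia at 8828 ± 127 and 7848 ± 195 CPM. For cytokines and chemokines 0 of 36 passed over all genes (camera, adjusted p = 0.25). Adjusted over the list alone, Tnfsf9, a costimulatory ligand gene, rose from 28.8 ± 5.5 to 62.4 ± 17.1 CPM, while Il6 was at 4.56 ± 1.08 and 9.49 ± 3.04 CPM. Over all genes, and leaving aside fits with a term for the replicate number, Tnfsf9 was called in 4 of 20 alternatives and Il6 in 1, the fit without a filter. The inflammasome and pyroptosis list (camera, adjusted p = 0.34), the pattern recognition and phagocytic receptors (0.35) and the chemotaxis and adhesion receptors (0.26) held 0 passing members by either adjustment. The scavenger receptor gene Msr1 was at 2.78 ± 1.20 and 10.6 ± 5.7 CPM and was not called in the main test. It was called without a filter, by DESeq2 and in the 2 fits with a term for the replicate number.

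The type I interferon list had a camera adjusted p of 0.11 and 0 of 46 members called, and the interferon gamma and antigen presentation list had 0.11 and 0 of 36. In the latter, the class I genes H2-Q7 (8.58 ± 0.89 to 19.5 ± 3.2 CPM) and H2-Q6 (8.42 ± 1.52 to 18.1 ± 3.6 CPM) rose adjusted over the list alone, and these genes have close relatives with which reads can be shared. Over all genes, and leaving aside fits with a term for the replicate number, H2-Q7 (edgeR adjusted p = 0.064) was called in 5 of 20 alternatives and H2-Q6 (0.15) in 3 of 20. At the preset correlation of 0.01, camera called both interferon lists higher without wild-type replicate 2 (adjusted p = 6.0e-16 and 0.0018). It also did so without knockout replicate 2 (0.00097 for each), so the outcome at that setting turned on these 2 libraries. Over all libraries the estimated correlation was 0.64 and 0.33, and with it camera called neither list (adjusted p = 0.85 and 0.74). The fits with a library left out were not repeated with it, so these small p-values may overstate the evidence.

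Neutrophil effector and maturation lists did not pass in camera. The adjusted p was 0.35 for primary granule proteins, 0.35 for secondary and tertiary granule proteins, 0.48 for calprotectin, stefins and metal withholding, 0.25 for NADPH oxidase, 0.17 for oxidative stress defence, 0.99 for extracellular trap formation, 0.60 for immature and 0.11 for mature and aged neutrophil genes. Adjusted over the list alone, Prdx1, a peroxide-reducing enzyme gene, rose from 10.03 ± 2.89 to 21.9 ± 5.4 CPM, and the transferrin gene Trf and the metallothionein gene Mt1 fell, from 15.9 ± 1.2 to 9.79 ± 0.52 CPM and from 32.1 ± 9.6 to 17.4 ± 4.0 CPM. Over all genes Prdx1 and Mt1 were called without a filter and by DESeq2, and Prdx1 also in the 2 fits with a term for the replicate number. Metabolic and housekeeping lists gave 0.11 for glycolysis, 0.11 for hypoxia response, 0.11 for oxidative phosphorylation, 0.11 for mitochondrially encoded genes, 0.47 for cytosolic ribosomal proteins, 0.47 for eicosanoid synthesis and 0.34 for cholesterol synthesis and efflux. Apoptosis and survival (0.92), immediate early and heat shock genes (0.64) and cell cycle (0.92) did not pass. In the apoptosis list Bmf, a proapoptotic gene that lies within 15 Mb of Il1a, fell adjusted over the list alone from 3.56 ± 1.44 to 0.67 ± 0.37 CPM, and was called over all genes without a filter and by DESeq2. For immediate early genes and extracellular trap formation the direction of the test and the sign of the median differed.

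Leaving out 1 library brought several of these lists past the threshold in camera with the preset correlation of 0.01. These fits were not repeated with an estimated correlation. Over all libraries that estimate ranged, among the lists below, from 0.023 for mature neutrophil genes to 0.89 for mitochondrially encoded genes. With it, 0 pathway lists were called. Glycolysis was called lower without wild-type replicate 1 (adjusted p = 0.017), wild-type replicate 2 (0.042) and knockout replicate 2 (0.0032), and hypoxia response without wild-type replicate 1 (0.0088) and knockout replicate 2 (0.00046). Mitochondrially encoded genes were called higher without wild-type replicate 1 (0.0023) and knockout replicate 1 (0.0044), and mature neutrophil genes lower without the same libraries (0.034 and 0.031). Oxidative phosphorylation was called lower without wild-type replicate 3 (0.030) and knockout replicate 1 (0.046), cytokines and chemokines higher (0.0023) and secondary granule proteins lower (0.0071) without knockout replicate 1, and oxidative stress defence higher without knockout replicate 2 (0.045).

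Neutrophil markers dominated all libraries, with S100a9 at 14129 ± 1390 and 13296 ± 897 CPM and S100a8 at 10316 ± 1076 and 9665 ± 508 CPM in wild type and knockout (SD, n = 3 each). The neutrophil list did not pass (camera, adjusted p = 0.076). Of 11 marker lists, 1 was called: monocyte and macrophage markers were higher in the knockout (camera with a preset correlation, adjusted p = 9.1e-06, median log2 fold change 1.40). The call was lost with an estimated correlation (adjusted p = 0.49), by fry (adjusted p = 0.52) and with only the 7 members that pass a filter at 5 CPM (camera, adjusted p = 0.22). The mean log2 CPM of the list was 1.63 to 1.90 in wild type and 1.79, 2.95 and 2.76 in knockout replicates 1, 2 and 3, and without knockout replicate 2, the library that stood apart, the list was still called at the preset correlation (camera, adjusted p = 0.00095). Of 18 tested members, 0 passed over all genes, and adjusted over the list alone 6 rose and 1 fell. The complement gene C1qb rose in that sense from 0.99 ± 0.26 to 4.81 ± 3.17 CPM, Pf4 from 2.63 ± 0.58 to 8.78 ± 4.08 CPM and F13a1 from 4.62 ± 1.60 to 17.0 ± 11.6 CPM, all 3 named for the list after their values were seen. Pf4 is on the erythroid and platelet list as well. Over all genes, all 3 were called without a filter and by DESeq2, Pf4 also without knockout replicate 1, and F13a1 also in the 2 fits with a term for the replicate number. The member that fell, Lyve1, went from 2.08 ± 2.10 to 0.22 ± 0.12 CPM and was likewise named after its values were seen. Over all genes it too was called without a filter and by DESeq2. The most abundant members were not called, with Csf1r at 178 ± 12 and 206 ± 22 CPM, Ctsl at 109 ± 7 and 93.4 ± 6.0 CPM and Adgre1 at 68.3 ± 13.3 and 79.4 ± 7.1 CPM.

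**Figure D3:**
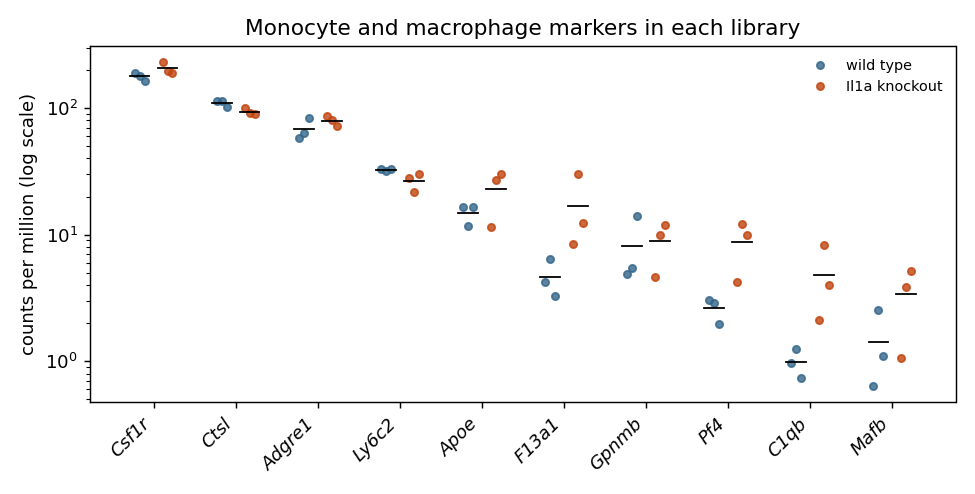
Expression in CPM (log scale) of monocyte and macrophage markers with a mean of at least 2 CPM, for 3 wild-type and 3 Il1a knockout libraries. Points are libraries and bars are group means. Csf1r, Ctsl and Adgre1 lie close together in both groups, while C1qb, Pf4 and F13a1 have higher means in the knockout and a wide spread among its libraries.

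The other marker lists did not pass in camera, with adjusted p of 0.076 for dendritic cells, 0.13 for eosinophils, mast cells and basophils, 0.33 for erythroid cells and platelets, 0.52 for melanocytes and neural cells, 0.62 for B and plasma cells, 0.79 for endothelium, 0.79 for epithelium, 0.94 for T, NK and innate lymphoid cells and 0.94 for keratocytes and fibroblasts. Adjusted over the list alone, Ccr7 rose in the dendritic list (1.06 to 5.18 CPM), Pf4 rose in the erythroid and platelet list, and Lyve1 fell in the endothelial list. Epithelial keratin Krt14 varied widely within each genotype, at 41.9 ± 39.5 and 34.2 ± 26.2 CPM. The epithelial list was called lower by camera without wild-type replicate 1 (adjusted p = 0.020) or knockout replicate 2 (0.0010). The dendritic list was called higher without wild-type replicate 3 (0.0032) or knockout replicate 1 (0.0028), with the 5 members that pass a filter at 5 CPM (0.0033) and without the genes near Il1a (0.048). The neutrophil list was called lower without the same 2 libraries (0.019 and 0.00030) and without the genes near Il1a (0.046), and the keratocyte list was called higher without knockout replicate 1 (0.035). These calls used the preset correlation. Over all libraries the estimated correlation was 0.67 for epithelium, 0.14 for dendritic cells, 0.16 for neutrophils and 0.31 for keratocytes and fibroblasts.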

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

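Removal of the genes near Il1a and the alternatives for marker lists were chosen after the data were seen; the others were planned. The loss of Il1a kept its direction and its call in all 21 alternatives run. The count of 12 changed genes became 185 without a filter, 21 with the filter at 5 CPM, 29 with strand column 1, 70 with DESeq2, 1 without the genes near Il1a (which removes 10 called genes) and 7 to 24 with each library left out. Except for the removal of those genes, the cause was not tested. Haus2, Ckap2l, Gm14023, Gm14085 and Stard9 stayed called in each alternative that tested them. Gm14023 was at a log2 fold change of -6.18 to -2.65, a range that takes in the strand columns, where reads shared with Il1a count to it. Pcna-ps2 was lost with limma-voom. Snap23, Bloc1s6 and Ehd4 were lost at a minimum fold of 1.5 and Eif3j2 without the genes near Il1a. Taking out called genes makes the adjustment stricter for the rest, so the loss of Eif3j2 does not show that it depends on that region. Of 3341 alternative values of uncalled named genes, 54 had another sign. The 1 called pathway list became 0 with an estimated correlation, 0 with fry and 0 to 6 with each library left out. The 1 called marker list became 0 with an estimated correlation, 0 with fry, 3 without the genes near Il1a and 1 to 4 with each library left out; with the filter at 5 CPM it was the dendritic list (0.0033) instead. The replicate numbers share no stated origin, deviations of same-numbered libraries correlated at 0.14, 0.057 and 0.0034, and not every sample correlated best with its own number. With the replicate block the count was 20 genes, 26 with the GC and length offset added, and 3 marker lists, with dendritic (0.0074) and neutrophil (0.037) added. The simulated test, with 200 genes changed, recovered 22% of 1.5-fold changes in genes with a mean of at least 5 CPM. With the 12 genes called in the data, recovery may be lower. The simulation does not separate depth from the spread between libraries.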

Other observations

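Apart from the count over splits of the libraries, the tests of explanations in this part were chosen after the results were seen, as was the 15 Mb distance, and the tests for neutrophil share, for reads shared with copies and for reads of Il1a counted to its neighbours were reworked once after further values were seen.

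Several genes, picked after their values were seen, did not pass the main test but were called in some of the alternatives. Gdf15, a stress-induced cytokine gene, was at 8.63 ± 2.09 CPM in wild type and 24.7 ± 6.7 CPM in the knockout (SD, n = 3 each; edgeR adjusted p = 0.070), and the noncoding RNA Neat1 at 1345 ± 172 and 2326 ± 362 CPM (edgeR adjusted p = 0.12). Eif5a, a translation factor gene, was at 601 ± 83 and 359 ± 11 CPM (edgeR adjusted p = 0.079), and the transcription factor gene Ets1 at 61.8 ± 3.3 and 38.0 ± 3.5 CPM (edgeR adjusted p = 0.12). The arginine transporter gene Slc7a2 was at 1.27 ± 0.23 and 7.29 ± 4.27 CPM (edgeR adjusted p = 0.12). Leaving aside fits with a term for the replicate number, Gdf15 and Eif5a were each called in 6 of 20 alternatives, Neat1 in 4 of 20, Slc7a2 in 4 of 19 and Ets1 in 2 of 20, among them DESeq2 and the fit without a filter for all 5.

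The real grouping of the 6 libraries gave 12 changed genes, 1 of the 10 splits giving as many, and the highest of the other splits gave 10. These 10 splits are too few for a share under 0.05. The split with 10 set wild-type replicates 1 and 2 and knockout replicate 1 apart from the rest and had 1353 genes at an unadjusted p under 0.05, against 714 for the genotypes. The libraries may thus hold a structure that the labels do not name, but this split was picked as the highest and the structure was not tested.

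Changed genes lay near Il1a: besides Il1a, 9 of 178 tested genes within 15 Mb and 2 of 11745 elsewhere were called. A candidate explanation is a chromosome segment carried with the deleted allele that differs in sequence between the genotypes. Among uncalled genes, an unadjusted p under 0.05 was found for 17.8% within 15 Mb, 5.72% on the rest of chromosome 2 and 5.72% on other chromosomes (odds ratio 3.55, 95% interval 2.29 to 5.35; 1.67, from 0.69 to 3.47, at 5 Mb, and 2.07, from 1.41 to 2.95, at 30 Mb), although strain backgrounds are not given and effects of the deletion on distant genes stay open and untested. For the 2 changed genes elsewhere, reads shared with copies near Il1a may account for the change: both had such a copy, as did 50 of all 11745 genes there, and the log2 ratio of the summed level of the pair was -0.067 for Eif3j2 and -0.035 for Pcna-ps2. The means of both copies were lower in the knockout, at an unadjusted edgeR p of 0.0014 for Eif3j1 and 0.16 for Pcna. Neither copy was called lower over all genes (edgeR adjusted p = 0.31 and 0.93), so the tables leave this open.

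Ckap2l and Gm14023 fell with Il1a. Fewer dividing cells are argued against by the cell cycle list, whose median log2 fold change was 0.13 with quartiles of -0.24 and 0.50. Ckap2l was at 49.1 CPM in wild type, 3.09 times the highest cell cycle gene, Pcna. Reads of Il1a transcription may have been counted to these genes, but the tables cannot decide this, since they do not show where in a gene the reads lie. Over 3 wild-type libraries the Ckap2l to Il1a count ratio varied 0.83 times as much as the share of Il1a itself. The Gm14023 to Il1a ratio varied 0.99 times as much. In summed strand columns it varied 0.062 times as much, and Gm14023 stayed at 23.7% to 24.4% of Il1a. There a read in the overlap counts to both genes, so this steadiness was largely set by shared reads. It does not show whether Gm14023 follows Il1a.

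Monocyte and macrophage markers were higher in the knockout by camera with a preset correlation, with 14 of 18 members above 0. The call was lost with an estimated correlation (adjusted p = 0.49) and by fry (0.52). The 4 members below 0 were Lyve1, Ctsl, Ly6c2 (32.6 and 26.5 CPM in wild type and knockout) and Fcgr1 (1.59 and 1.26 CPM). Ly6c2 and Fcgr1 were named after their values were seen. A source in knockout replicate 2 alone is argued against by replicate 3. Its mean log2 CPM was 2.76, above the wild-type range of 1.63 to 1.90, but replicate 1, at 1.79, lay within that range. Without replicate 2 the list was still called by camera with the same preset correlation (adjusted p = 0.00095, and 2.1e-14 to 0.00095 with each library left out). The estimated correlation over all libraries was 0.18, and these fits were not repeated with it, so the calls cannot decide this. A lower share of neutrophils cannot be told apart from the rest here. The genotype difference of these markers exceeded that of structural markers by 0.75 (two-sided exact permutation p = 0.3, smallest possible 0.1). Without knockout replicate 2 the epithelial list was called lower (camera with the preset correlation, adjusted p = 0.0010). Its estimated correlation over all libraries was 0.67. Its summed CPM ranged from 41.7 to 196 in wild type and from 50.8 to 190 in the knockout, so that call cannot decide this. More monocytes or macrophages among the sorted cells may also account for it, as may a change inside neutrophils, and the 14 members above 0 do not separate these. The cells were sorted as neutrophils, but how many other cells passed the sort was not tested. The most abundant markers, Csf1r, Ctsl and Adgre1, were not called, at 178, 109 and 68.3 CPM in wild type. A rise as small in CPM as that of C1qb, from 0.99 to 4.81, would be small against these levels, so they cannot decide this.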
